A study of Mus musculus with 7 samples.

How the data were processed

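Messenger RNA was measured in microdissected subpallium (the ganglionic eminences and the septum) of female CD-1 mouse embryos at embryonic day 12.5, with 1 embryo per array. The labels give 4 control arrays and 3 arrays labelled Otx2 cKO, in which a floxed Otx2 allele was recombined by RxCre. The embryos came from 4 litters: litter 2 gave control replicates 2 and 3 and cKO replicates 1 and 3, while control replicate 1, control replicate 4 and cKO replicate 2 were each the only embryo of their litter. The files place the arrays on 2 slides. Slide 1 held control replicates 1 and 2 and cKO replicate 1, and slide 2 held control replicates 3 and 4 and cKO replicates 2 and 3.

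Per the labels' protocols, total RNA was amplified, labelled with Cy3 and hybridised to Agilent whole mouse genome arrays, so each array has a single colour. Per the file headers, the intensity of each spot was background-subtracted and detrended within its array by Agilent Feature Extraction 10.7.3.1, and nothing was normalized between arrays; the submitters' processing notes name Agilent Feature Extraction 10.5. The authors also deposited a table of log2 values whose scale is not given in the sources used here. Within each array its order of probes followed the median spot signal without background subtraction (rank correlation at least 0.99996), and the columns shared a maximum of 18.8, as quantile normalization gives; the column medians were 7.61, 7.63, 7.61 and 7.62 for control replicates 1 to 4 and 7.62, 7.62 and 7.64 for cKO replicates 1 to 3. No centring or direction was left to settle there, because the values follow the signal itself. This table served as an alternative.

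Each array held 45018 spots, of which 43379 were not controls and carried 41174 probes. Control spots were left out, and so were spots that the scanner software marked as outliers (1.24% to 2.51% per array). No spot was saturated. Between 68.4% and 72.2% of spots were well above background, and 13.1% to 16.7% had a processed signal at or below 0. The processed signal was divided by the array's 75th percentile, floored at 1 common level (log2 value -7.45, the highest of the arrays' lowest signals among probes well above background) and taken to log2. Values are therefore log2 signals relative to the array's 75th percentile. Replicate spots of a probe were averaged. The number of arrays limits the precision of every value.

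The files carry accessions and no gene symbols, so probes were named through RefSeq accessions in a gene table of the GRCm38.p6 assembly, used for names and gene order only. Of the 41174 probes 24844 had 1 symbol, 0 had several and 16330 had none; 94.2% of the probes with a RefSeq accession were named. A gene was represented by its brightest probe and tested when that probe was well above background on at least 3 of the 7 arrays. Of 17178 named genes 13539 passed this filter, and 13339 had enough unflagged values to be tested. Where a gene was not well above background on any array of a group, the difference is given as a bound ("at least N-fold"), the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the array's lowest signal among probes well above background and the probe's own signal.

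The single comparison, arrays labelled Otx2 cKO against control, was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term) and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Errors given as SE are limma's moderated standard errors; the estimated prior degrees of freedom were 1.86 and the median SE of a log2 difference was 0.13. Before the data were examined, 24 gene lists with 354 genes and no gene in more than 1 list were fixed: MGE identity, LGE and CGE identity, pan-subpallial GABAergic, septal and rostral midline, FGF ligands and response genes, SHH pathway, cortical hem and WNT/BMP, choroid plexus, pallial, Cajal-Retzius, hypothalamic with preoptic and optic, thalamic with midbrain and hindbrain, oligodendrocyte lineage, radial glia and Notch, cell cycle, pan-neuronal, cholinergic, erythroid, endothelial, mesenchyme and pericyte, microglia and macrophage, immediate early and heat shock, hypoxia and glycolysis, and p53 targets. Of the 354 genes 301 were tested, 36 were below the background filter, 4 had too few unflagged values and 13 had no named probe. Lists were tested with camera at a preset inter-gene correlation of 0.01 on the 12671 genes with a value on every array, adjusted over the 24 lists, and again with an estimated correlation and with fry. A list's shift is the median log2 difference of its members in that test.

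The rule for the genes named, also fixed beforehand, was Otx2, then up to 12 genes that rose and 12 that fell with the largest log2 differences among those past the threshold with every cKO-labelled array beyond every control array, then in each list up to 4 members past the threshold or, where none was, the 2 members with the smallest p as values only. Any other gene named was chosen after its values were seen. Some genes that the rule names are not reported here, and they stay in the counts of genes and the list tests but not in the check for single control arrays that lie apart.

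The alternatives fixed beforehand were quantile normalization, median centring, no background filter, a filter requiring all 7 arrays, the mean of a gene's probes, the authors' value table, a variance trend with robust estimation, array weights, slide as a block and each slide alone, litter as a fixed block, as a random block and litter 2 alone, the replicate number as a block, the 2 other list tests, and leaving out each array. The planned normexp correction (offset 50) was run on the median spot signal, since the mean spot signal it was written for is not a column of these files. That change, a floor 4 times lower, flagged spots kept, every probe tested on its own and the mesenchyme list median as a covariate were chosen after seeing the data, as were the floor itself, the restriction to named genes and the handling of flagged spots. The fit was tested on simulated data drawn for the 12671 genes with the real means and spreads, with 200 genes changed. For this comparison it called 67.0% of the 2-fold and 93.0% of the 4-fold changes, 4.76% of its calls were unchanged genes, and it called 0 genes where nothing had been changed. The simulated noise was independent between genes and arrays, without slide, litter or mesenchyme structure. These rates need not hold for the real arrays.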

Results

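Gene expression was profiled in the subpallium of 7 female mouse embryos at E12.5, 4 controls and 3 labelled as conditional knockouts of Otx2 (Otx2 cKO). Otx2 encodes a homeodomain transcription factor of the anterior neural plate and forebrain. RxCre recombines the floxed allele in most of the forebrain but, per the series description, spares a caudal dorsomedial part with the choroid plexus and the cortical hem. The comparison asks which genes depend on Otx2 in the ganglionic eminences, the source of striatal, pallidal and interneuron lineages, and in the septum. Each array measured 1 embryo. The log2 values of 2 arrays correlated at 0.987 to 0.993 among controls, 0.984 to 0.990 among cKO-labelled arrays and 0.980 to 0.992 between the groups.

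The Otx2 probe itself was higher, not lower, in the arrays labelled Otx2 cKO. Its log2 signal was 0.19, 0.55, 0.48 and 0.56 in control replicates 1 to 4 and 1.78, 2.34 and 1.77 in cKO replicates 1 to 3, a difference of 1.52 ± 0.17 (SE, n = 4 and 3; limma, adjusted p = 0.0356). This was 2.87-fold higher, with all 3 cKO-labelled arrays above all 4 controls. The signal of the targeted gene therefore ran against the label. Which part of the gene the floxed allele removes, and whether the probe lies inside it, is not given in the sources used here; a probe outside the deleted part checks nothing about the genotype. The groups are called by their labels throughout, and every direction below rests on those labels. The Otx2 difference was 1.41 within slide 1, which holds 1 cKO-labelled array and 2 controls, and 1.54 within slide 2, which holds 2 and 2, and 1.49 with slide as a block (adjusted p = 0.0766). It was 1.26 within litter 2, and leaving out any 1 array kept it between 1.33 and 1.62 but ended the call in each case (adjusted p 0.0559 to 0.156; over 26 alternatives 0.00619 to 1, with 11 past the threshold).

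In the arrays labelled Otx2 cKO, 11 genes rose and 17 fell, 0.21% of the 13339 genes tested, and 23 of the 28 changed at least 2-fold. Otx2 was 1 of the 11. Hmx3 and Hmx2, homeobox genes of the hypothalamus and inner ear, rose by 2.12 ± 0.23 and 1.73 ± 0.17 on the log2 scale (adjusted p = 0.0298 and 0.0237). The dorsal neural tube gene Msx3 rose by 1.37 ± 0.16. The imprinted zinc finger gene Zim1 rose by 1.65 ± 0.13, and Metap1d, a mitochondrial methionine aminopeptidase, by 1.26 ± 0.13. Calcr, the calcitonin receptor, rose by 1.002 ± 0.081, although its second, dimmer probe differed by only 0.28. P2rx7, an ATP-gated channel, rose by 1.05 ± 0.13 on its brighter probe while the other, dim probe differed by -0.27. Ccnb1ip1 and the formin gene Diaph3 rose by 0.85 ± 0.10 and 0.80 ± 0.098.

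Prdm16, a zinc finger regulator of neural stem cells, had the largest measured decrease among the genes that fell. It fell by 2.97 ± 0.23, a 7.85-fold difference (adjusted p = 0.0152). Lhx8, a LIM homeobox gene of the medial ganglionic eminence and its cholinergic neurons, fell by 2.04 ± 0.17, and its second probe gave -2.19. The homeobox genes Gbx2 and Gbx1 fell, with differences of -1.90 ± 0.16 and -1.47 ± 0.13. Tal2, a basic helix-loop-helix gene, fell by 2.28 ± 0.28, and Olig1, another such gene, of the oligodendrocyte lineage, fell by 1.44 ± 0.10. Nxph2, which encodes a neurexophilin, was not well above background on any cKO-labelled array and was at least 6.72-fold lower there (adjusted p = 0.0267). That bound holds for the main processing only: the log2 difference of Nxph2 ran from -3.83 to -0.84 over 25 alternatives. Among genes of the cell surface and matrix, Megf11, the protease gene Adamts5, Elfn1 and the GABA-B receptor subunit gene Kctd8 fell, with differences of -1.79 ± 0.21, -1.29 ± 0.16, -1.28 ± 0.13 and -1.21 ± 0.12. The adrenergic receptor gene Adra1b fell by 1.32 ± 0.11 on its brighter probe, while a dim probe differed by 0.22. Nxph1, Lhx6, Gnrh1, Stac2 and C1qtnf12 made up the rest; all but Nxph1 lie outside the rule for named genes and were chosen after their values were seen. Gnrh1, which encodes gonadotropin-releasing hormone, fell by 1.16 ± 0.092, and Stac2 and C1qtnf12 differed by -0.96 ± 0.093 and -0.72 ± 0.075.

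**Figure D1:**
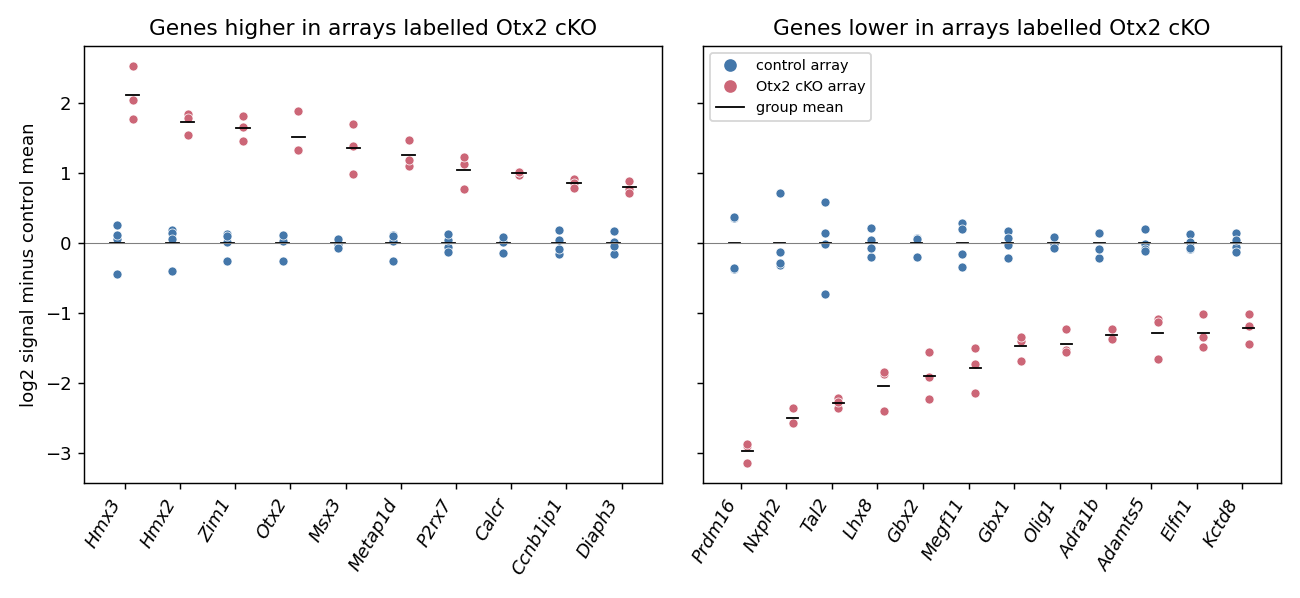
Log2 signal of each named gene in each array, minus the mean of the 4 control arrays, for named genes that rose and the 12 genes that fell with the largest differences; points are arrays and short lines are group means. For each gene the 3 cKO-labelled arrays lie beyond the 4 controls, from 2.12 for Hmx3 to -2.97 for Prdm16; Nxph2 in cKO-labelled arrays was not well above background.

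All 28 genes had every cKO-labelled array outside the control range, as did 12.8% of all genes against 5.71% by chance. The count depended on single arrays: limma called 0 genes without control replicate 2, control replicate 3, control replicate 4 or cKO replicate 3 (532, 449, 465 and 401 genes higher and 765, 626, 998 and 465 lower at an unadjusted p under 0.05), 3 without cKO replicate 2 (323 and 970), 11 without control replicate 1 (423 and 730) and 25 without cKO replicate 1 (895 and 1001). With all arrays 526 were higher and 947 lower at that unadjusted p. With slide as a block 16 genes were called. Within slide 2 limma called 0 (546 higher and 647 lower at an unadjusted p under 0.05), and within litter 2 0 (214 and 630). All 28 genes kept their direction in these fits and within slide 1. That was fixed beforehand, since each had every cKO-labelled array outside the control range.

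The genes of the medial ganglionic eminence (MGE) formed the list with the smallest p. Of 17 measured members of the MGE identity list 5 fell, 0 rose and 12 did not pass the test; adjusted over the list alone, 11 fell and 0 rose. Besides Lhx8, Gbx1 and Elfn1, these were Nxph1, which fell by 0.86 ± 0.085, and Lhx6, the LIM homeobox gene of MGE-derived interneurons, which fell by 1.18 ± 0.15 (adjusted p = 0.0237 and 0.0491). The neuropeptide genes of interneurons had values of -3.50 ± 0.52 for Sst and -1.45 ± 0.19 for Npy and passed only over the list alone. Nkx2-1, the homeobox gene that specifies the MGE, differed by 0.13 ± 0.20, and Nkx6-2 by 0.23 ± 0.33, neither past the test. The list's median was -0.86 over the 15 members with a value on every array (camera, adjusted p = 2.45e-13; adjusted p = 0.022 with an estimated correlation), and the per-array medians were -0.75, -0.60 and -0.79 in cKO replicates 1 to 3 against -0.07 to 0.08 in controls. The shift was -0.85 with slide as a block, -0.83 within slide 1, -0.75 within slide 2 and -0.84 within litter 2, and it passed the threshold in all 28 alternatives, where the slide 1 fit has no spread among cKO-labelled arrays, having 1. These alternatives are not all separate checks. The variance trend left the list test unchanged, and litter as a block rests on litter 2 alone. The 2 other list tests share the main shift. It was smaller in the authors' value table (-0.55), with flagged spots kept (-0.59), with the mean of a gene's probes (-0.67) and without cKO replicate 3 (-0.67), and the median over all 17 measured members was -0.64.

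**Figure D2:**
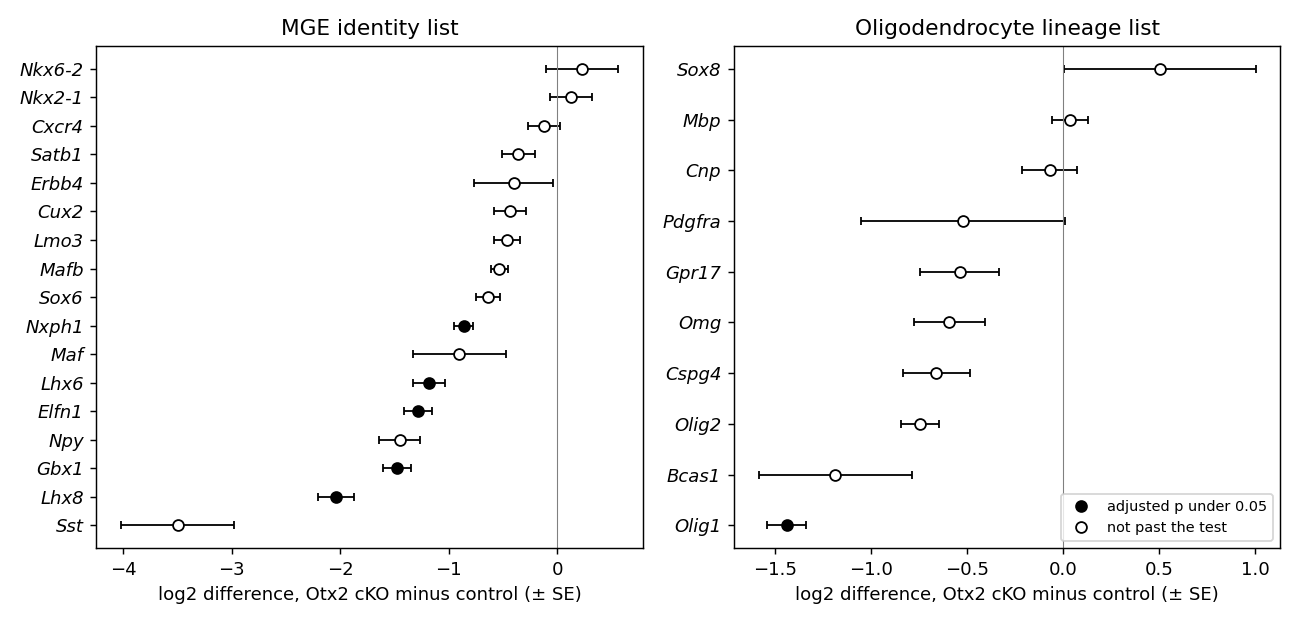
Log2 difference (Otx2 cKO minus control, with its SE) of tested members of the MGE identity and oligodendrocyte lineage lists; filled points passed the test over all genes. Members of the MGE list spread from -3.50 for Sst to 0.23 for Nkx6-2, and those of the oligodendrocyte list from -1.44 for Olig1 to 0.50 for Sox8.

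The oligodendrocyte lineage list was also lower. Of 11 measured members 1 fell, Olig1, and 10 did not pass; over the list alone Olig1, Olig2, Cspg4, Bcas1 and Omg fell. Olig2 differed by -0.74 ± 0.10. The median was -0.54 (camera, adjusted p = 0.00302; adjusted p = 0.359 with an estimated correlation). The shift was -0.60 with slide as a block, -0.34 within slide 1, -0.54 within slide 2 and -0.71 within litter 2; with 1 cKO-labelled array, slide 1 gives a value without a spread in that group.

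The 3 other lists past the preset test contained no gene past the test over all genes. The pan-neuronal list shifted by -0.17 (adjusted p = 0.00302; adjusted p = 0.809 with an estimated correlation), with 14 of 17 members negative and a value of -0.36 ± 0.091 for the neuronal tubulin gene Tubb3. The pan-subpallial GABAergic list shifted by -0.27 (adjusted p = 0.019; adjusted p = 0.809 with an estimated correlation), a median over 9 members that was -0.13 over all 11 measured; over the list alone Gad1 and Gad2, which encode the enzymes of GABA synthesis, fell, with differences of -0.67 ± 0.13 and -0.34 ± 0.078, while Dlx1 and Dlx2 had values of -0.13 and -0.10. The cell cycle list shifted by 0.17 (adjusted p = 0.0424; adjusted p = 0.809 with an estimated correlation), with 14 of 15 members positive and values of 0.23 ± 0.10 for Cdk1 and 0.25 ± 0.13 for Mki67. Fry's directional test called the MGE and oligodendrocyte lists but not these 3. Its test without direction gave an adjusted p of 0.0486 for pan-neuronal, 0.002 for pan-subpallial and 0.17 for cell cycle. The pan-neuronal, pan-subpallial and cell cycle shifts were -0.15, -0.24 and 0.11 with slide as a block, -0.16, -0.20 and 0.10 within slide 1 (not called, adjusted p = 0.307 for each), -0.21, -0.29 and 0.18 within slide 2, and -0.16 (not called), -0.22 and 0.07 (not called) within litter 2. Leaving out cKO replicate 2 ended the pan-neuronal call (-0.10, adjusted p = 0.145) and the pan-subpallial call (-0.15, adjusted p = 0.108); leaving out control replicate 2 or 3 ended the pan-subpallial call (adjusted p = 0.055 and 0.063); leaving out control replicate 1 or cKO replicate 3 ended the cell cycle call (0.10 in both, adjusted p = 0.12 and 0.186). Median centring ended the pan-subpallial and cell cycle calls (-0.37 and 0.07, adjusted p = 0.0817 and 0.102) and moved the pan-neuronal shift to -0.27, and the mean of a gene's probes ended the same 2 calls (-0.07 and 0.13, adjusted p = 0.065 and 0.142). The cell cycle call was also lost with litter as a block, as a random block and with the mesenchyme covariate (0.07, 0.16 and 0.17, adjusted p = 0.189, 0.0808 and 0.0572), the pan-neuronal call with litter as a block (-0.16, adjusted p = 0.207) and the pan-subpallial call with the replicate block (-0.31, adjusted p = 0.0651).

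Lists for other regions of the forebrain and brain did not pass the preset test as lists, though single members changed. Fry's test without direction, which lets members move both ways, passed for several. Its adjusted p was 8e-05 for septal, 8e-05 for Cajal-Retzius, 0.000339 for thalamic and 0.00112 for hypothalamic. It was 0.0279 for pallial and 0.0324 for LGE and CGE, but 0.606 for cortical hem and 0.746 for choroid plexus. That test gives a list no direction. Of the 19 lists not called, of any kind, 15 had a median of the other sign in at least 1 alternative. In the septal and rostral midline list Prdm16 fell and the 7 other measured members did not pass; the zinc finger genes Zic2 and Zic5 had values of 0.05 and 0.12 (list median -0.07, adjusted p = 0.315). Within litter 2 that list was called lower (-0.33, adjusted p = 0.0271; 0.00676 to 0.969 over its alternatives). The hypothalamic, preoptic and optic list had a median of 0.04, which was -0.05 under median centring (adjusted p = 0.418); over the list alone Nkx2-2 fell, with a difference of -1.59 ± 0.38. In the thalamic, midbrain and hindbrain list Gbx2 fell and 6 members did not pass (median 0.16, adjusted p = 0.953); over the list alone En2 and Irx1 rose, with differences of 3.01 ± 0.88 and 0.64 ± 0.18. Of 25 measured LGE and CGE genes 0 passed, over all genes or over the list alone (median -0.02, adjusted p = 0.420), with values of -0.51 ± 0.12 for Tac1 and -0.55 ± 0.17 for Bcl11b.

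Pallial and Cajal-Retzius lists held members of both signs. The pallial list had a median of -0.02 over the 15 genes in its test (adjusted p = 0.768); over the list alone the neuronal genes Neurod6 and Neurod2 fell, at -0.76 ± 0.16 and -0.80 ± 0.18, and the progenitor gene Emx2 rose, at 0.56 ± 0.13. The 9 Cajal-Retzius genes had a median of 0.13 (adjusted p = 0.315), and over the list alone Nhlh2 and Lhx5 rose, at 0.44 ± 0.071 and 0.59 ± 0.15, while Trp73 fell, at -0.37 ± 0.11. No member of the following signalling lists passed over all genes. The SHH pathway list had a median of 0.16 (adjusted p = 0.124), with 0.18 ± 0.084 for Smo. The FGF list had a median of 0.20, which was -0.001 in the authors' value table (adjusted p = 0.768); Fgf15 differed by -0.72 ± 0.14 and fell over the list alone, and Fgf3 differed by -0.52 ± 0.16. The cortical hem and WNT/BMP list had a median of -0.24 (adjusted p = 0.568), which was 0.16 without cKO replicate 1, with -0.49 ± 0.19 for Rspo3 and -1.94 ± 0.75 for Rspo1. The choroid plexus list had a median of 0.19 (adjusted p = 0.420), which was -0.20 without cKO replicate 2, with 0.63 ± 0.38 for Kl and 0.68 ± 0.43 for Prlr. The radial glia and Notch list had a median of 0.05, which was -0.05 under median centring (adjusted p = 0.420), with 0.57 ± 0.18 for Hes1 and -0.27 ± 0.087 for Ednrb. The cholinergic list had a median of -0.18 (adjusted p = 0.420); Ache differed by -0.63 ± 0.15 and fell over the list alone, and Ngfr differed by -0.47 ± 0.36, with 0.06 on its other probe.

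Markers of non-neural cells varied widely between embryos of both groups. The per-array median of the mesenchyme and pericyte list, relative to the control mean, was 0.44, -1.81, 0.57 and 0.83 in control replicates 1 to 4 and -1.43, 1.89 and -0.99 in cKO replicates 1 to 3. The first principal component, with 35.1% of the variance, placed control replicate 2 and cKO replicate 1 at 31.3 and 27.2 and cKO replicate 2 at -40.3. In cKO replicate 2 the medians of the FGF, hem, choroid plexus, endothelial, microglia and erythroid lists were 1.03, 0.98, 0.74, 0.63, 0.60 and 0.62, the highest of the 7 arrays in each. None of these lists passed the test between groups: the adjusted p was 0.420 for mesenchyme and pericyte (median -0.34; Dcn -2.72 ± 1.85, Rgs5 -0.50 ± 0.36), 0.420 for endothelial (median -0.14; Robo4 -0.42 ± 0.18 but 0.007 in the authors' value table, Slco1c1 -0.84 ± 0.45), 0.783 for microglia and macrophage (median -0.14; Aif1 0.24 ± 0.23, Cx3cr1 -0.18 ± 0.26) and 0.315 for erythroid (median 0.18; Tspo2 0.36 ± 0.16, Epb42 0.78 ± 0.42). Without cKO replicate 2 the mesenchyme, endothelial and microglia lists were called lower, with medians of -0.99, -0.52 and -0.45, but without cKO replicate 1 their medians were 0.30, 0.04 and 0.09, not called. The endothelial list was also called lower with array weights (-0.41). The erythroid list was called higher with the mesenchyme covariate and without cKO replicate 3 (0.23 and 0.38), but its median was -0.14 without cKO replicate 2. With the mesenchyme median as a covariate, an alternative chosen after seeing the data, 3 genes rose and 11 fell, 13 of them among the 28, and the MGE shift was -0.84.

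**Figure D3:**
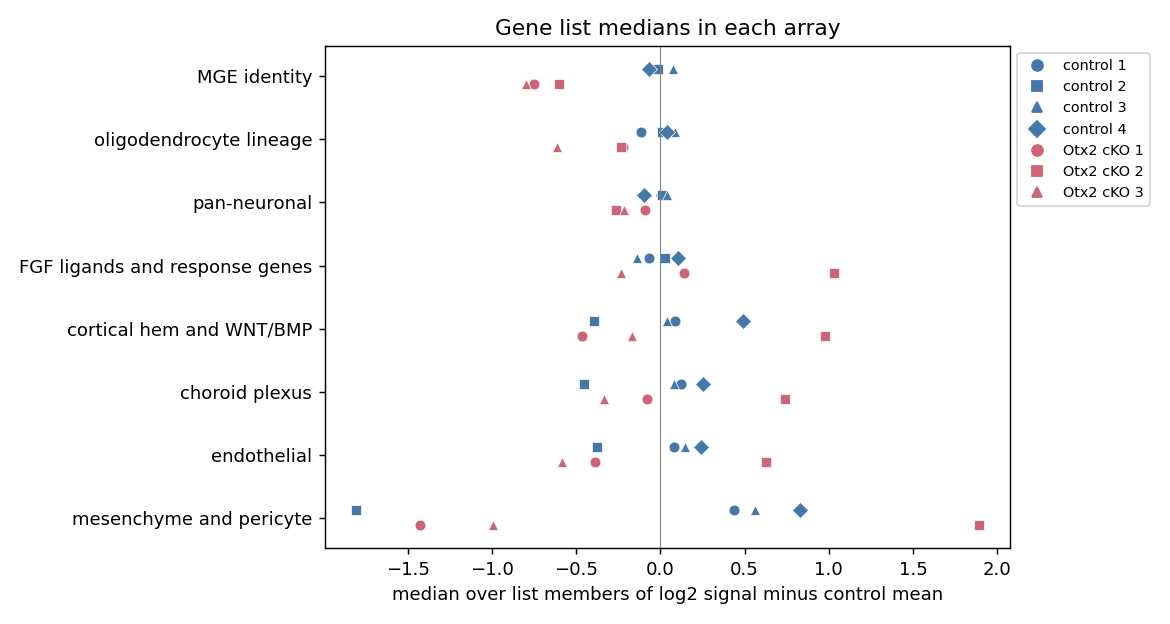
Median over the members of 8 gene lists of log2 signal minus the control mean, in each of the 7 arrays; colour gives the group and marker shape the replicate. The MGE medians of the 3 cKO-labelled arrays lie between -0.79 and -0.60, below all controls, while the mesenchyme medians run from -1.81 to 1.89 across both groups.

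Lists for tissue handling and stress did not pass the preset test with all arrays in the main fit. Fry's test without direction passed for hypoxia and glycolysis (adjusted p = 0.0472) but not for the other lists here. The immediate early and heat shock list had a median of 0.10 (adjusted p = 0.420), with 0.92 ± 0.41 for Fosb and 0.27 ± 0.18 for Hspa1a. The hypoxia and glycolysis list had a median of 0.12 (adjusted p = 0.0569) with 11 of 12 members positive, and it was called higher in 5 of its 28 alternatives: the authors' value table (0.14, adjusted p = 0.0388), no background filter (0.0151), flagged spots kept (0.0226), and without control replicate 3 (0.22, adjusted p = 0.0315) or cKO replicate 3 (0.0459); Pdk1 differed by 0.48 ± 0.14 and Ldha by 0.25 ± 0.090, with a value near 0 on its other probe. The p53 target list had a median of 0.01 with a negative mean and test direction (adjusted p = 0.953) and a median of -0.08 under median centring; Cdkn1a differed by -0.39 ± 0.14 and Trp53inp1 by -0.21 ± 0.077, with 0.25 on its other probe. The labels give all embryos as female: Xist was well above background on all 7 arrays and 4 Y-linked genes on 0.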

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

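The tests of a mislabelled array, of choroid plexus and hem tissue, of exchanged labels, of the MGE share, litter, slide and neurons in general, and the counts over other splits were chosen after the results they bear on had been seen. The Otx1 and mesenchyme covariate tests were written before their results were seen, for patterns noticed in the same data.

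Among the 4 control arrays, 1 array lay far from the other 3 for 7 of the 81 genes and lists examined (8.64%, where chance gives about 5%). The ratio of the gap to the whole range was 0.96 for Gbx2 with control replicate 4 apart, 0.84 for Neurod2 with control replicate 1 and 0.86 for Ldha with control replicate 3. It was 0.89, 0.83 and 0.90 for the medians of the SHH pathway list, of the thalamic, midbrain and hindbrain list and of the cell cycle list, each with control replicate 1 apart. For the mesenchyme and pericyte list it was 0.85, with control replicate 2 apart. Groups of 3 were not examined. Of 8886 probes without a gene symbol, which the counts of genes leave out, 3 passed the test when every probe was tested on its own, with log2 differences of -1.49, 1.91 and -1.58.

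The Otx2 probe was higher in the arrays labelled Otx2 cKO. One mislabelled array would leave a value out of place, and 0 of the 7 arrays lay nearer the other group's mean. This count restates the separation of the groups already given and adds no further evidence. More choroid plexus and hem tissue is argued against by the 2 cKO-labelled arrays whose medians for both lists lay below the control mean: the lower of their Otx2 values was still 1.33 above the control mean. Signal of the paralog Otx1 stays open, because the Otx1 probe differed by 0.70 ± 0.18, below the rise of Otx2 but not clear of the bound set for it. An exchange of all labels cannot be told apart from a probe that still detects the recombined allele's transcript, with more of it made, since the files hold no other record of genotype beside the difference of 1.52; under exchanged labels every sign would turn.

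The genes of the MGE list were lower in the arrays labelled Otx2 cKO. A smaller share of MGE in the dissection would lower its markers alike, and the median difference of Nkx2-1, Nkx6-2 and Shh was 0.13, against -0.86 for the list. Nkx2-1 and Nkx6-2 are members of that list, and the 3 genes were picked after their values were seen. Whether other tissue gave part of their signal was not tested. Younger cKO litters are argued against as the whole cause by a shift of -0.84 within litter 2, slide by -0.85 with slide as a block, and mesenchyme content by -0.84 with that covariate. Fewer neurons in general would lower the pan-neuronal list as well. Its median was -0.17, above -0.43, the MGE shift divided by 2, by slightly more than the SD over its members (0.24). That SD is a spread over genes, not embryos. The pan-neuronal and MGE medians were -0.27 and -0.96 under median centring, and -0.20 and -0.55 in the authors' value table. In cKO replicates 1 to 3 the pan-neuronal median was -0.09, -0.27 and -0.22, against -0.75, -0.60 and -0.79 for the MGE list. The margin does not settle how much of the shift fewer neurons could give. That genes of postmitotic MGE cells, such as Lhx6, Lhx8 and Sst, may depend on Otx2 is a hypothesis that no test here checks directly; fewer such cells and less transcript per cell were not separated, and the open question over the labels applies to the direction.

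All 35 ways of splitting the 7 arrays into 4 and 3 were fitted. For the 11 genes higher, 1 split, the real one, gave as many, and the highest other count was 4. That is the smallest share 35 splits can give, in a test chosen after the result was seen. The splits also ignore slide and litter, so the real split ranked first but chance is not excluded. For the 17 genes lower, 3 splits gave as many and the highest other count was 138; for the 23 genes changed at least 2-fold it was 3 splits and 70; for the 5 lists called it was 17 splits and 12, so chance cannot be excluded for these counts. The MGE shift of -0.86 was matched by 1 split, the real one, and the largest other shift was 0.71 in size. The same limits hold for this shift: the real split ranked first but chance is not excluded. The 18 splits that keep 1 array of the group of 3 on slide 1 are too few for a share under 0.05; the highest other values among them were 4 genes higher, 1 lower, 3 at 2-fold, 12 lists and an MGE shift of 0.61 in size. The split with 138 genes lower sets control replicates 1 and 2 and cKO replicate 1 against the rest. It is the one between the 2 slides, which points to a structure that follows slide. The split with 37 lower groups control replicate 2 with cKO replicates 1 and 3. These 3 arrays have the lowest mesenchyme medians, and all 3 also came from litter 2, as did control replicate 3. This split does not separate mesenchyme from litter. With slide as a block 5 genes were higher and 11 lower; slide 1 holds 1 cKO-labelled array and slide 2 holds 2, so the 0 calls within each slide decide nothing here.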

How the results depend on the processing

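The alternatives named as chosen after seeing the data in the methods are normexp on the median signal, the lower floor, flagged spots kept, every probe tested and the mesenchyme covariate. In the 26 alternatives fitted over genes, each of the 28 called genes that could be measured kept its direction. Without an array, within a slide or litter, or with slide, litter or replicate number as a fixed block, this had to hold. Each of the 28 genes had every cKO-labelled array outside the control range. The 5 lists called kept their direction in all 28 alternatives, the MGE list was called in all 28 and the oligodendrocyte list in 27. For a list these alternatives are not all separate checks, as given above. Of 596 values of the 23 called genes that the naming rule gives 266 stayed past the threshold and 330 did not; of 975 values of the 38 uncalled genes it gives 3 passed it and 7 had the other sign; of 532 values of uncalled lists 19 passed it (hypoxia and glycolysis 5, septal 4, erythroid 3, endothelial 2, and Cajal-Retzius, hypothalamic, mesenchyme, microglia and FGF 1 each) and 58 had the other sign. The cause of the following moves was not tested, except that fits within a slide or litter or without an array have fewer arrays, and slide 1 has 1 cKO-labelled array, which leaves no spread in that group. The genes higher, lower and changed at least 2-fold, 11, 17 and 23 with all arrays, were 4, 11 and 8 with no background filter, 18, 49 and 39 with array weights, 5, 11 and 14 with slide as a block and 3, 11 and 12 with the mesenchyme covariate. Normexp called 33 genes lower and a variance trend 37; the authors' value table called 17 higher and 26 lower; a floor 4 times lower and testing every probe each called 6 higher. Within slide 1, within slide 2, with litter as a block and within litter 2, limma called 0 higher, 0 lower and 0 at 2-fold, with 213, 546, 220 and 214 higher and 198, 647, 644 and 630 lower at an unadjusted p under 0.05. The Otx2 difference stayed positive but was no longer called with no filter (1.52, adjusted p = 0.0858), slide as a block (1.49, 0.0766), slide 1 alone (1.41, 1), slide 2 alone (1.54, 0.368), litter as a block (1.26, 0.303), litter 2 alone (1.26, 0.303) and the mesenchyme covariate (1.54, 0.0516). The lists called were 3 with median centring and with the mean of a gene's probes, 1 with an estimated correlation and 2 with fry's directional test. Leaving out each array gave 0 to 7 genes higher, 0 to 18 lower, 0 to 22 at 2-fold, 4 to 7 lists and an Otx2 difference of 1.33 to 1.62. The numbers of replicates in the labels did not pair the arrays: deviations from the group means correlated at 0.11, -0.53 and 0.03 for same-numbered arrays, and control replicate 2 correlated best with cKO replicate 1, at 0.37. With the replicate block, limma called 0 genes higher, 0 lower and 0 at 2-fold (600 higher and 897 lower at an unadjusted p under 0.05), the Otx2 difference was 1.56 (adjusted p = 0.321) and 4 lists were called. Signal near background limits Nxph2 to a bound, and 36 list genes were not tested for that reason.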

Other observations

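The genes in this part were chosen after their values were seen, and the test on the neighbours of Otx2 was set before its result was seen. At an adjusted p under 0.1, 20 genes were higher and 40 lower, the 28 called genes included. Bcan, which encodes the matrix proteoglycan brevican, differed by -3.28 ± 0.48 and Dgkg, a diacylglycerol kinase gene, by -3.38 ± 0.46, each lower in 3 of 3 cKO-labelled arrays than in any control. The basic helix-loop-helix gene Ptf1a, which specifies GABAergic neurons of the cerebellum and spinal cord, differed by 1.53 ± 0.24, and all 3 cKO-labelled arrays lay above the controls. None of these passed the threshold of 0.05 (adjusted p = 0.0845, 0.069 and 0.0982).

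Fgf8 and Fgf17, FGF ligand genes of the rostral midline, differed more among the cKO-labelled embryos than between the groups. The log2 signal of Fgf8 was -2.68, -0.33 and -4.57 in cKO replicates 1 to 3 and -2.45, -2.85, -2.83 and -1.53 in control replicates 1 to 4, an SD of 2.13 against 0.62. Fgf17 had an SD of 2.32 against 0.92, with its highest value, -2.81, in cKO replicate 2 as well. En2, an engrailed gene of the midbrain and hindbrain, was -2.05, -0.28 and -4.36 in the same arrays and -5.70 to -4.72 in controls. The FGF list was called higher without cKO replicate 3 (median 0.51, adjusted p = 0.0492; 0.0492 to 0.999 over its alternatives) and in no other alternative.

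Ccnb1ip1 lies on chromosome 14 with 9 tested genes between it and Otx2, which raised the hypothesis that flanking DNA of another strain, carried along with the floxed allele, may account for some changes near Otx2. Of the 100 tested genes nearest Otx2, 15 had an unadjusted p under 0.05 (15.0%, against 11.0% of all others). Ccnb1ip1, which raised the hypothesis, counts among the 15. The excess did not pass a one-sided Fisher's exact test (p = 0.135), which leaves the hypothesis open. Ccnb1ip1 was the 1 gene called among them, and Arhgap22, also among the 100, differed by 1.93 ± 0.25 (adjusted p = 0.0575).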
